A study of Homo sapiens with 6 samples.

How the data were processed

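The study measured gene expression in CUTLL1 cells by RNA sequencing. Per the labels' protocols, cells were transduced with lentiviral particles that carried Cas9 with a guide RNA against GLI1 (sgGLI1) or Cas9 alone (control), selected for 5 days in puromycin, purified for viable cells on a Ficoll gradient and grown for 3 more days before RNA extraction. The protocols name six-well plates with 3 replicates per group, lettered A to C, and do not say whether these came from separate transductions, so p-values measure the spread between these cultures, which may be technical. The control carried no guide, so that effects of breaking DNA as such were not separated from effects of losing GLI1. Whether the library kit kept RNA strand is not given in the sources used here, so counts of overlapping and antisense genes are uncertain, as are those of genes with near-identical copies such as the ribosomal protein genes.

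The submitters' processing notes name STAR 2.5.3a, HTSeq 0.12.3 and the genome build hg19. The deposited table of the whole series holds raw counts per gene, which the authors made per library, for 32754 genes of 8 annotation types. The deposited files of single samples hold FPKM values of the same genes. Dividing the counts by the FPKM and the library total gave the same gene length in all samples for 22821 of 22821 genes with counts (relative tolerance 1e-06), so the FPKM were used only for gene lengths. Columns of samples outside the study numbered 0. The table held 0 of 13 mitochondrially encoded genes looked for.

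Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group (14902 genes; 9933 genes had 0 counts in all libraries), scaled by TMM and tested with glmQLFit and glmQLFTest on the group alone, 3 against 3, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Changes of at least 2-fold had a log2 fold change of at least 1 in size. The SE of a log2 fold change was taken from the F statistic. CPM are counts scaled to 1e6 of the library total after TMM. Library totals ran from 51.3M to 91.0M (M, 1e6 counts), at which 3 counts correspond to 0.033 to 0.059 CPM. Ratios of genes near that floor come from summed counts divided by summed totals, with exact binomial 95% intervals that cover counting error only. Replicates differed by more than sampling noise in every pair within a group (chi-square per gene from 2.68 to 51.9). Differences in GC trend between libraries, given below, can add to this value, so it does not show that the libraries came from separate cultures. Each library was analysed as a separate sample. The biological coefficient of variation was 7.71%.

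Gene lists, the rule for named genes and the alternatives below, save those stated as added later, were fixed before the data were examined. The 33 lists were written from textbook knowledge for the hedgehog pathway, T cell leukaemia, glucocorticoid response, growth, stress, metabolism and markers of other cell types. Of their 1048 gene symbols, 1029 were found in the table, and 30 lists had at least 5 genes tested. Lists left out of the set test were those of mitochondrially encoded genes, with 0 genes tested, myeloid markers, with 3, and erythroid and megakaryocyte markers, with 2. The 30 lists were tested on log2 CPM with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and beside it with an estimated correlation and with fry, adjusted over the 30 lists. Of the 3 lists higher and 3 lists lower with the preset correlation, only that of nucleolar ribosome biogenesis held with the estimated one. Counts of members that rose or fell use the adjustment over all genes tested, and again an adjustment over the list alone.

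Genes were named by a fixed rule. It takes a panel of 12 genes (GLI1, GLI2, GLI3, PTCH1, SMO, SUFU, BCL2, NR3C1, NOTCH1, MYC, HES1 and IL7R). It adds the 12 genes with the largest fold change in each direction that passed the test, had a mean of at least 1 CPM and did not overlap between groups. It also takes up to 4 members of each list with the smallest p, passing members first, and the 5 genes with the smallest p in each direction.

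The alternatives were DESeq2 size factors, upper quartile scaling or library size alone in place of TMM, no filter or a filter of 1 CPM in 3 samples, a replicate block, leaving out each library in turn, DESeq2 1.42.0 and limma-voom. For lists these were an estimated correlation, fry and leaving out shared genes. A correction of each library for GC content and gene length, thinning of all libraries to the smallest total and leaving out genes of chromosome 14 were added after seeing the data. GC content was taken from the longest GENCODE 29 transcript of each gene (Biostrings 2.70.1), with a value for 96.5% of tested genes, and GENCODE 29 also gave the order of genes along chromosomes; no coordinates were carried between builds. The tests were run on simulated counts with the real means and library sizes, in which 200 genes were changed. For the comparison of sgGLI1 with control over 14743 genes, edgeR recovered 56.0% of genes changed 1.25-fold, 74.0% of those changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold, and 25 of its 187 calls (13.4%) were unchanged genes, above the 5% that the threshold aims at. A list shifted by -0.2 in simulated counts was found at -0.197 (camera adjusted p = 1.4e-27, and adjusted p = 0.012 with an estimated correlation), with 0 other lists called in camera. Genes were drawn independently in these counts and without GC trends, so they cannot show how many lists would be called by correlation between genes.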

Results

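RNA sequencing was performed on 6 cultures of CUTLL1, a cell line from a childhood T lymphoblastic lymphoma that grows as immature T cells. In 3 cultures the cells carried a lentivirus with Cas9 and a guide RNA against GLI1, a zinc-finger transcription factor at the end of the hedgehog pathway (sgGLI1). In the other 3 the lentivirus carried Cas9 without a guide (control). Total gene counts were 91.0M, 66.1M and 55.6M in control A, B and C, and 51.3M, 53.6M and 57.8M in sgGLI1 A, B and C (M, 1e6 counts). The comparison of both groups asked how the transcriptome differs when GLI1 is targeted.

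In sgGLI1 cells, the GLI1 transcript was 1.41-fold lower than in control cells and that of PTCH1, the hedgehog receptor and a direct GLI1 target, was 1.61-fold lower. The thymocyte surface genes CD1E and CD8A fell 2.24-fold and 2.10-fold. Of 48 nucleolar genes for ribosome biogenesis, 26 fell and 0 rose. Of 32 genes for cholesterol and fatty acid synthesis, 9 rose and 1 fell. Without control B or any single sgGLI1 library, 4 to 6 of these nucleolar genes fell and 4 or 5 of the lipid genes rose. In all, 811 genes were higher and 850 lower in sgGLI1 among 14902 tested, 87.3% of them by less than 2-fold.

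GLI1 (ENSG00000111087.5, chromosome 12) had 329, 196 and 157 counts in control A, B and C and 111, 117 and 136 in sgGLI1 A, B and C. This corresponds to 3.13 ± 0.42 CPM (SD, n = 3) in control and 2.24 ± 0.10 CPM (SD, n = 3) in sgGLI1. The log2 fold change was -0.49 ± 0.13 (SE), with an adjusted p of 0.047 in edgeR's quasi-likelihood test, and the groups did not overlap. A two-sided exact permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 samples allow. The GLI1 call was lost without control A, control B or any single sgGLI1 library (adjusted p from 0.12 to 0.16 in edgeR), and kept without control C (log2 fold change -0.55, edgeR adjusted p = 0.0097). It was also lost with upper quartile normalization (edgeR adjusted p = 0.052) and in limma-voom (adjusted p = 0.060). With each library corrected for GC content and gene length, the GLI1 call was kept at a smaller log2 fold change (-0.37, edgeR adjusted p = 0.036). A guide that causes small insertions or deletions need not lower the transcript, so its level does not measure how many alleles were edited.

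Among the other hedgehog genes, PTCH1 went from 34.1 ± 2.34 to 21.2 ± 0.98 CPM (SD, n = 3 each; log2 fold change -0.68 ± 0.07, edgeR adjusted p = 0.00078). KIF7, a kinesin that regulates GLI proteins in the cilium, fell by 1.24 on the log2 scale (edgeR adjusted p = 0.0033). HHIP, which binds hedgehog ligands, rose by 0.33 (edgeR adjusted p = 0.014). SMO, the signal transducer of the pathway, rose by 1.73 (edgeR adjusted p = 0.020) but had only 8 to 26 counts in control libraries and 28 to 45 in sgGLI1 libraries. GLI3 (log2 fold change -0.05 ± 0.06) and SUFU (-0.03 ± 0.07), a GLI inhibitor, did not pass the test, and GLI2 had 0 counts in all 6 libraries. Of 22 hedgehog pathway genes tested, 3 rose and 2 fell (4 and 3 adjusted over the list alone), and camera gave an adjusted p of 0.97. Of 14 known GLI targets tested, 1 rose and 5 fell (1 and 6 adjusted over the list alone), with an adjusted p of 0.31 in camera. The target that rose was HHIP, and both HHIP and PTCH1 are counted in the pathway list as well. Besides PTCH1, the targets that fell include BMP4, a secreted growth factor encoded on chromosome 14, which went from 59.9 ± 7.31 to 32.9 ± 0.51 CPM (SD, n = 3 each). CCNE1, the cyclin that drives entry into S phase, fell by 0.53 on the log2 scale. The calls of HHIP and SMO were lost without control B (adjusted p = 0.074 and 0.086 in edgeR), sgGLI1 B or sgGLI1 C, and that of SMO also without sgGLI1 A. In these 4 fits 0 to 2 hedgehog genes rose and 2 fell, and 0 or 1 GLI target rose and 3 fell. Without control C, 5 hedgehog genes rose and 3 fell.

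**Figure D1:**
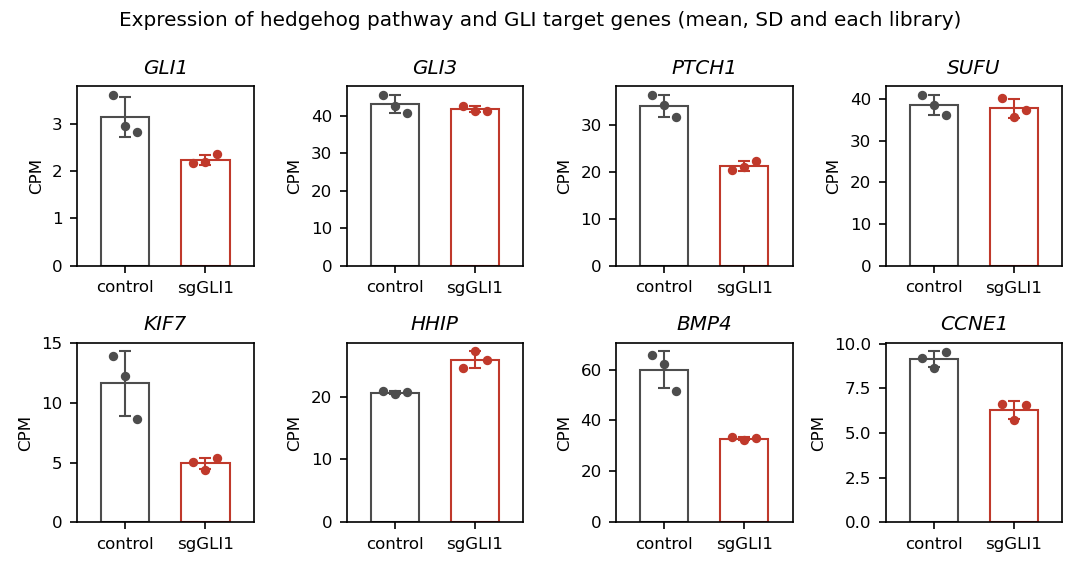
Expression in CPM (counts scaled to 1e6 per library, y axis from 0) of 8 hedgehog pathway and GLI target genes in control (grey) and sgGLI1 (red); bars are means of 3 libraries, error bars are SD and points are single libraries. PTCH1, KIF7, BMP4 and CCNE1 lay lower in each sgGLI1 library than in each control library, HHIP lay higher, and GLI3 and SUFU overlapped.

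SESN3 apart, the genes with the largest rises had low levels in control cells. STON2, an endocytic adaptor, went from 3, 0 and 2 counts in control to 95, 133 and 129 in sgGLI1, a ratio of 93.4 after division by the totals (95% counting interval 39.6 to 289). KREMEN1, a receptor for the WNT inhibitor Dickkopf, rose 11.4-fold to 8.91 ± 1.18 CPM (SD, n = 3). CCDC11, a gene of motile cilia, rose by 3.16 on the log2 scale, and ZNF621, which encodes a zinc-finger protein, by 2.27. The other largest rises were those of RP11-11N9.4 (6.25-fold), SEL1L3 (3.61-fold), BHLHE40 (3.49-fold), EXPH5 (3.01-fold), SESN3 (2.74-fold), GALNT11 (2.67-fold), LINC00467 (2.66-fold) and TMEM156 (2.65-fold). SESN3, a stress-induced FOXO target, was the most abundant of these, at 25.3 ± 2.23 CPM in control and 69.4 ± 2.25 CPM in sgGLI1 (SD, n = 3 each; edgeR adjusted p = 1.4e-05). ABHD4, a lipid hydrolase, rose by 1.35 on the log2 scale and GLUL, glutamine synthetase, by 1.30, both among the 5 smallest p-values of the genes that rose. STON2 and ABHD4 lie on chromosome 14, whose 516 tested genes had a median log2 fold change of 0.14.

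Among the genes with the largest falls, CYSLTR2, a leukotriene receptor, went from 188, 171 and 167 counts to 2, 1 and 1 (ratio 101, 95% counting interval 39.0 to 370). WDR35, a component of intraflagellar transport, went from 286, 231 and 197 counts to 1, 4 and 5 (ratio 54.6, 95% counting interval 29.5 to 114). SFRP2, a secreted WNT antagonist, fell 7.68-fold, FASLG, the death ligand of T cells, 7.23-fold, and CLIC4, an intracellular chloride channel protein, 7.08-fold. Further large falls were those of THSD7A (5.98-fold), AGPAT3 (4.89-fold), GPRASP1 (4.23-fold), L3MBTL1 (4.23-fold), GTF2IRD1 (4.15-fold) and VAV3 (3.90-fold). The abundant genes ADAM22, an adhesion protein of the ADAM family, and CD1E had the smallest p-values of all genes. ADAM22 went from 334 ± 24.0 to 92.0 ± 3.99 CPM and CD1E from 608 ± 13.8 to 271 ± 6.44 CPM (SD, n = 3 each; edgeR adjusted p = 2.1e-06 for both). Of the genes with the largest changes, only TMEM156 lost its call in any fit with 1 library left out (adjusted p = 0.051 in edgeR without control B).

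**Figure D2:**
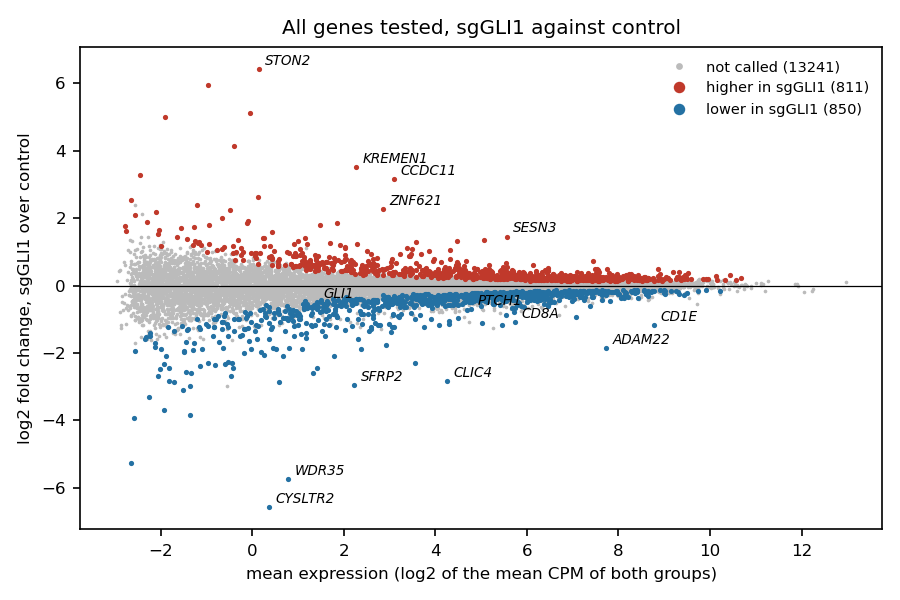
Log2 fold change of sgGLI1 over control (y axis) against mean expression (x axis, log2 CPM) for the 14902 genes tested; red points are the 811 genes higher and blue points the 850 genes lower in sgGLI1, grey points did not pass. Most changed genes lie within 1 of 0 on the log2 scale, and 71 genes higher and 140 genes lower lie beyond it.

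Genes of nucleolar ribosome biogenesis were lower. In the nucleolar ribosome biogenesis list, 46 of 48 genes were below 0 and 26 fell (34 adjusted over the list alone), with a mean log2 fold change of -0.23 and a camera adjusted p of 2.2e-11, or adjusted p = 0.038 with an estimated correlation. In fry, a self-contained test, the adjusted p was 0.00090. Without control B, 6 of these genes fell, and without sgGLI1 A, B or C, 5, 4 and 6, while camera's call was kept without each library (largest adjusted p 1.7e-07). Members were BYSL (-0.32 ± 0.05), URB2 (-0.38 ± 0.06), PES1 (-0.27 ± 0.04) and RRP12 (-0.57 ± 0.09), all factors in the assembly of ribosomal subunits. Of 40 MYC targets, 1 rose and 7 fell (4 and 16 adjusted over the list alone), with a camera adjusted p of 0.0061 and adjusted p = 0.22 with an estimated correlation. Their fry adjusted p was 0.0031. Without control C, 6 MYC targets rose and 18 fell, and without control B or any single sgGLI1 library 0 rose and 1 or 2 fell. Without control A, 3 rose and 5 fell. The MYC targets that fell include ODC1, the first enzyme of polyamine synthesis (-0.33 ± 0.04), and FKBP4 (-0.23 ± 0.04). MYC itself went from 299 ± 45.1 to 230 ± 8.23 CPM (SD, n = 3 each; log2 fold change -0.38 ± 0.10, edgeR adjusted p = 0.040). Its call was kept without control C (log2 fold change -0.49) and lost without each of the other libraries (edgeR adjusted p from 0.067 without control A to 0.16 without control B) and in limma-voom (adjusted p = 0.051). The call of PES1 was lost without sgGLI1 A or B (edgeR adjusted p = 0.050 and 0.051), and that of FKBP4 without sgGLI1 A or C (edgeR adjusted p = 0.051 for both). Of 53 cytosolic ribosomal protein genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone), RPS25 by 0.38 and RPL32 by 0.23 on the log2 scale. Their calls were lost without control B (edgeR adjusted p = 0.083 and 0.087), sgGLI1 A (0.080 and 0.11) or sgGLI1 C (0.083 and 0.096), and that of RPL32 also without sgGLI1 B (0.081). Without control C, 22 of the 53 rose and 14 fell. Without control A 3 rose, without sgGLI1 B 1 rose, and without control B, sgGLI1 A or sgGLI1 C 0 rose, with 0 that fell in these 5 fits. With each library corrected for GC content and gene length, 36 ribosome biogenesis genes fell and 0 rose, 5 MYC targets rose and 14 fell, and 19 ribosomal protein genes rose and 0 fell. The ribosomal protein list did not pass in camera (adjusted p = 0.11), but passed without control A (camera adjusted p = 0.023) or sgGLI1 B (camera adjusted p = 0.022).

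Among cell cycle genes that passed the test, those of G1/S and DNA replication fell and most of those of mitosis rose. Of 46 genes for G1/S and DNA replication, 6 fell and 0 rose (7 and 0 adjusted over the list alone), among them CCNE1, MCM4 (-0.14 ± 0.03) and GINS4 (-0.22 ± 0.06); the camera adjusted p was 0.0061, and adjusted p = 0.22 with an estimated correlation. The fry adjusted p was 0.0040. This call was lost without control C (camera adjusted p = 0.089), in which fit 4 of these genes rose and 16 fell, and 1 gene fell without control B or any single sgGLI1 library. The calls of MCM4 and GINS4 were lost without control B or any single sgGLI1 library (edgeR adjusted p from 0.093 to 0.17), and that of GINS4 also without control A (0.074). MCM4 and GINS4 did not pass with upper quartile normalization (edgeR adjusted p = 0.069 and 0.059), nor MCM4 in DESeq2 (adjusted p = 0.060). Of 48 genes for G2/M and mitosis, 6 rose and 1 fell (10 and 3 adjusted over the list alone), with a camera adjusted p of 0.010 and adjusted p = 0.83 with an estimated correlation. In fry the adjusted p was 0.20. DLGAP5, a spindle protein encoded on chromosome 14 (0.33 ± 0.06), PRC1 (0.18 ± 0.04) and KIF2C (0.18 ± 0.04) rose, whereas CCNB1, the mitotic cyclin, fell by 0.20 on the log2 scale. These 4 calls were lost without control B or any single sgGLI1 library (edgeR adjusted p from 0.056 to 0.12), in which 4 fits 0 genes of the list passed. Without control C, 30 rose and 6 fell. With the GC and length correction, 18 of them rose and 4 fell, and 2 G1/S genes rose and 17 fell. Of 18 replication-dependent histone genes, 0 passed the test in edgeR, DESeq2 or limma-voom (0 adjusted over the list alone, 2 at an unadjusted p under 0.05; camera adjusted p = 0.39). The most abundant, HIST1H1C, averaged 3.33 CPM over all libraries and passed without control C (log2 fold change -0.41, edgeR adjusted p = 0.018), in which fit 2 histone genes fell.

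In the glucocorticoid response list, 8 of 34 genes rose and 2 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.029, and adjusted p = 0.22 with an estimated correlation). The fry adjusted p was 0.0024. CD53, a tetraspanin of lymphocytes, rose 2.07-fold, and TNFAIP3, an inhibitor of NF-kB signalling, and BMF, a pro-apoptotic BCL2 family member, rose by 0.41 each on the log2 scale. BCL2L11, the pro-apoptotic protein BIM and a main mediator of steroid-induced death in lymphoid cells, fell 1.28-fold. NR3C1, the glucocorticoid receptor (0.06 ± 0.05), and BCL2 (0.09 ± 0.04) did not pass the test (edgeR adjusted p = 0.47 and 0.20). The list's call was lost without control C, sgGLI1 A or sgGLI1 C (camera adjusted p = 0.089, 0.084 and 0.063) and when only its 21 genes that are in no other list were tested (camera adjusted p = 0.44). Of 17 BCL2 family genes, 3 rose and 2 fell (3 and 5 adjusted over the list alone), and of 31 p53 targets, 3 rose and 1 fell (3 and 2 adjusted over the list alone), with camera adjusted p of 0.97 and 0.82. TNFRSF10B, a TRAIL receptor, rose 1.48-fold and AEN, a nuclease of apoptotic cells, fell 1.33-fold. Of 26 FOXO targets and quiescence genes, 6 rose and 3 fell (9 and 4 adjusted over the list alone; camera adjusted p = 0.15), led by SESN3, with KLF6 falling 1.54-fold and BCL6 rising 1.29-fold. This list passed in fry as higher (adjusted p = 0.0045). Without control C, 11 glucocorticoid response, 8 FOXO, 4 BCL2 family and 4 p53 genes rose, and 5, 6, 6 and 5 fell. Without control B or any single sgGLI1 library, 6 glucocorticoid response, 2 or 3 FOXO, 1 BCL2 family and 1 p53 gene rose, and 1, 2, 1 and 1 fell. Without control A, 1 BCL2 family gene fell. With the GC and length correction, 11 glucocorticoid response, 10 FOXO, 4 BCL2 family and 7 p53 genes rose, and 5, 4, 4 and 3 fell.

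Most of the lipid genes that passed the test rose. Of 32 genes for cholesterol and fatty acid synthesis, 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a camera adjusted p of 0.029 and adjusted p = 0.22 with an estimated correlation. INSIG1, the sterol-sensing retention protein, rose 1.40-fold, SCD, the stearoyl-CoA desaturase, 1.31-fold, and FADS2, a fatty acid desaturase, 1.30-fold. The list's mean was -0.001 while its median was 0.05 and camera's direction was up. The fry adjusted p was 0.014. The call was lost without control C, sgGLI1 A or sgGLI1 C (camera adjusted p = 0.12, 0.077 and 0.082). Without control B or any single sgGLI1 library 4 or 5 of these genes rose and 1 fell, and without control C 12 rose and 4 fell. After the GC and length correction 13 rose and 3 fell.

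CD1E, CD8A and CD8B were among the T cell genes that fell. Of 41 T cell and thymocyte genes, 5 rose and 7 fell (7 and 12 adjusted over the list alone; camera adjusted p = 0.60). The list passed in fry as lower (adjusted p = 0.032). Without control B or any single sgGLI1 library 0 of these genes rose and 4 to 6 fell, and without control C 8 rose and 15 fell. With the correction for GC content and gene length more of them rose than fell, 14 against 11. CD8A went from 72.2 ± 4.74 to 34.4 ± 0.71 CPM and CD8B from 160 ± 3.97 to 126 ± 2.80 CPM (SD, n = 3 each), and RAG1, a subunit of the antigen receptor recombinase, fell by 0.29 on the log2 scale. CCR9, the chemokine receptor for homing to thymus and gut, fell 1.70-fold, S1PR4, a sphingosine-1-phosphate receptor, fell from 119 to 12 counts summed over 3 libraries (ratio 7.58, 95% counting interval 4.18 to 15.1), and CD44 rose 1.38-fold. Of 27 homing and adhesion genes, 2 rose and 2 fell (2 and 5 adjusted over the list alone; camera adjusted p = 0.60). Of 29 genes of T cell activation, 1 rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.97), with IER5, an immediate early gene, falling by 1.89 on the log2 scale. Without control C, 2 homing genes rose and 6 fell, and 4 activation genes rose and 9 fell. Without control B or any single sgGLI1 library, 1 homing gene rose and 2 fell, and 0 activation genes rose and 1 fell. Without control A, 1 activation gene rose and 1 fell. With the GC and length correction, 9 homing genes rose and 6 fell, and 3 activation genes rose and 2 fell. Of 12 T-ALL transcription factors, 0 passed the test in edgeR, DESeq2 or limma-voom (0 adjusted over the list alone, 4 at an unadjusted p under 0.05; camera adjusted p = 0.86). Without control C 3 of these rose and 3 fell, among them NKX2-5, a homeobox factor (log2 fold change -1.38, edgeR adjusted p = 8.1e-05), and TCF3, an E protein (-0.61, edgeR adjusted p = 4.2e-05). Without control A 1 rose, and with the correction for GC content and gene length 1 rose and 2 fell.

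NOTCH1, the receptor whose active form drives T-ALL, had 1262, 1058 and 685 CPM in control A, B and C and 692, 633 and 740 CPM in sgGLI1 A, B and C. It did not pass the test (log2 fold change -0.54 ± 0.18, edgeR adjusted p = 0.089), whereas without control C its log2 fold change was -0.74 (edgeR adjusted p = 1.1e-05). It also passed when each library was corrected for GC content and gene length (log2 fold change -0.33, edgeR adjusted p = 0.0069) and with no filter on low counts (edgeR adjusted p = 0.019). Of 25 NOTCH targets, 2 rose and 4 fell (3 and 8 adjusted over the list alone; camera adjusted p = 0.39). Without control C 4 of these rose and 13 fell, and without control B or any single sgGLI1 library 1 or 2 rose and 0 or 1 fell. After the GC and length correction 4 rose and 7 fell. RASGRP1, an activator of RAS in T cells, rose by 0.34 on the log2 scale and GIMAP5, a GTPase of lymphocyte survival, fell 1.55-fold, the latter call being lost without control B (edgeR adjusted p = 0.051). HES1 (-0.16 ± 0.08) and IL7R, the interleukin-7 receptor (-0.02 ± 0.05), did not pass (edgeR adjusted p = 0.22 and 0.78), though HES1 passed without control C (log2 fold change -0.21, edgeR adjusted p = 0.035).

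In the interferon response list, 2 of 34 genes rose and 3 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.80). The genes that fell were PARP9 (2.22-fold), DTX3L (1.88-fold) and PARP14 (2.44-fold), while MX2, an antiviral GTPase, rose 1.21-fold. The call of PARP14 was lost without sgGLI1 A or C (edgeR adjusted p = 0.057 and 0.058). The NF-kB target list had 3 genes that rose and 0 that fell of 21 (3 and 0 adjusted over the list alone; camera adjusted p = 0.36), TNFAIP3, BIRC3 (1.37-fold) and NFKBIA (1.17-fold, on chromosome 14). Of 16 antigen presentation genes, 0 rose and 1 fell (0 and 1 adjusted over the list alone; camera adjusted p = 0.36). Of 37 integrated stress response genes, 5 rose and 1 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.35, fry adjusted p = 0.0045), including the mitochondrial folate enzyme MTHFD2, which rose 1.30-fold. Heat shock genes gave 2 that rose and 5 that fell of 25 (2 and 7 adjusted over the list alone; camera adjusted p = 0.39), HSPH1 by 0.43 on the log2 scale. Of 31 genes of the ER unfolded protein response, 4 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p = 0.86). Glycolysis and hypoxia genes gave 3 that rose and 6 that fell of 37 (9 and 8 adjusted over the list alone; camera adjusted p = 0.97), the glucose transporter gene SLC2A3 rising 1.59-fold and P4HA1 falling 1.30-fold. Of 51 oxidative phosphorylation genes, 1 rose and 1 fell (1 and 1 adjusted over the list alone; camera adjusted p = 0.36), and of 36 lysosome and autophagy genes, 3 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.39). With the correction for GC content and gene length, the NF-kB and integrated stress response lists passed in camera as higher (adjusted p = 0.0083 and 0.026).

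The number of genes called in these lists changed when 1 library was left out and with the GC and length correction. Fits with 5 libraries have fewer samples, so fewer calls there need not come from the library left out. Without control C, 9 interferon response genes rose and 7 fell, with 4 and 4 for NF-kB targets, 1 and 6 for antigen presentation, and 12 and 6 for the integrated stress response. In the same fit, 5 heat shock genes rose and 8 fell, with 8 and 4 for ER stress, 10 and 10 for glycolysis and hypoxia, 6 and 13 for oxidative phosphorylation, and 9 and 9 for lysosome and autophagy. Without control B or any single sgGLI1 library, 1 interferon response gene rose and 2 or 3 fell, with 3 and 0 for NF-kB targets, 0 and 0 for antigen presentation, and 2 and 0 for the integrated stress response. In these 4 fits, 0 or 1 heat shock gene rose and 1 or 2 fell, 0 or 1 ER stress gene rose and 0 fell, and 2 glycolysis genes rose and 1 or 2 fell. For oxidative phosphorylation 1 rose and 0 fell, and 0 lysosome genes passed. Without control A, 1 interferon response gene rose, and 6 lysosome genes rose and 0 fell. With the GC and length correction, more genes rose than fell for glycolysis and hypoxia (10 against 8) and interferon response (9 against 5). In that fit the counts were 7 and 2 for NF-kB targets, 2 and 3 for antigen presentation, 12 and 2 for the integrated stress response, and 4 and 7 for heat shock. They were 5 and 2 for ER stress, 3 and 8 for oxidative phosphorylation, and 7 and 1 for lysosome and autophagy.

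No tested marker list of another cell type passed in camera. Of 6 B cell markers tested, 1 fell (1 adjusted over the list alone; camera adjusted p = 0.86), POU2AF1, a coactivator of octamer factors, by 0.54 on the log2 scale. Summed over 16 B cell markers, expression was 131, 122 and 114.5 CPM in control A, B and C and 95.5, 90.3 and 89.8 CPM in sgGLI1 A, B and C, most of it from POU2AF1. Of 8 markers of NK and innate lymphocytes, 0 passed the test in edgeR, DESeq2 or limma-voom (0 adjusted over the list alone, 2 at an unadjusted p under 0.05; camera adjusted p = 0.39). Of 6 epithelial and stromal markers, 0 passed in these tools and 1 fell adjusted over the list alone (1 at an unadjusted p under 0.05; camera adjusted p = 0.90). Without control C, 1 NK marker rose and 2 fell, and with the GC and length correction 2 rose and 0 fell. In edgeR 1 epithelial or stromal marker fell without control A, without control C or with the GC and length correction. Lists too small to test were those of myeloid markers (144, 130.5 and 158 CPM summed in control, 163, 160 and 168 CPM in sgGLI1), of erythroid and megakaryocyte markers (13.9, 12.35 and 11.2 CPM against 13.6, 13.4 and 13.4 CPM) and of mitochondrially encoded genes, with 0 genes in the table. The myeloid sum was higher in each sgGLI1 library than in each control library, but only 3 of the 22 markers were tested. Mean, median and the direction of camera differed in sign for the lists of cholesterol synthesis, hedgehog pathway, T-ALL factors, T cell activation, homing, p53 targets, BCL2 family, interferon response, ER stress, B cell and epithelial markers.

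**Figure D3:**
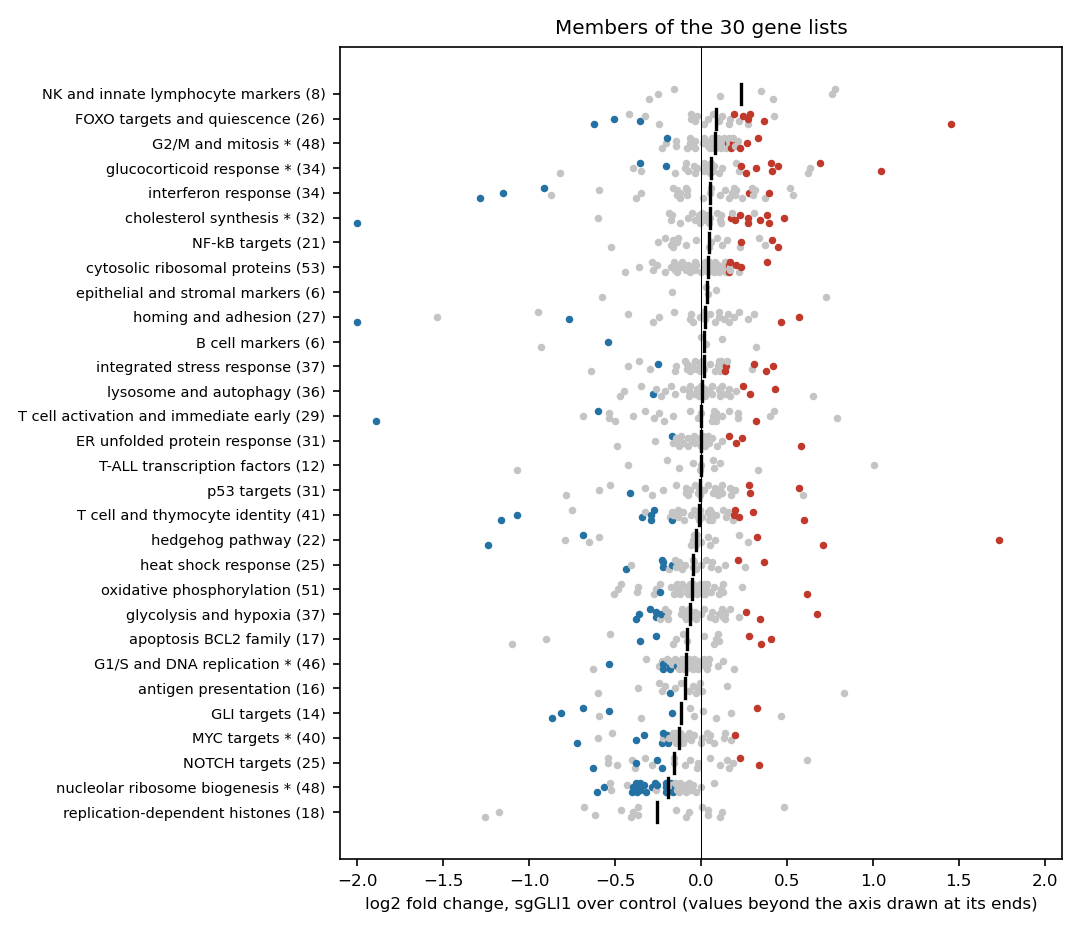
Log2 fold change of sgGLI1 over control (x axis) of each tested member of the 30 gene lists, with the number of members in brackets; red and blue points passed the test as higher and lower, grey points did not, and black lines are list medians. An asterisk marks the 6 lists with a camera adjusted p under 0.05, and the ribosome biogenesis list has 26 blue points and 0 red points.

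The test was edgeR's quasi-likelihood F-test with Benjamini-Hochberg adjustment. Of the genes tested, 71 were higher and 140 lower by at least 2-fold, and 34.3% had no overlap between groups, against 10% by chance. With upper quartile normalization 1113 genes were higher and 679 lower, so that 62.1% of calls were higher against 48.8% with TMM. Leaving out 1 library changed the number of genes called, from 1661 with all 6 libraries to 476 without control B, 512, 477 and 510 without sgGLI1 A, B and C, and 5027 without control C. On a principal component analysis the first component (49.2% of variance) separated the groups, and the second (18.9%) separated control C from the other libraries. Log2 fold changes followed the GC content of genes (Spearman's rho -0.33 across genes, which are not independent replicates), and so did differences between libraries of the same group, up to 0.65 between control A and control C. The correlation was 0.56 between control A and control B and 0.43 between control B and control C, so control C was not alone in this trend. Leaving out control C also changes the GC trend between the groups. How far this adds to the calls in fits without control C was not tested.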

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

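The tests of single libraries and of segments of the chromosome were chosen only after the result was seen. The chromosome given for each gene, which the comparisons by gene and list did not use, showed a difference between the groups above the level among control libraries. The 516 tested genes of chromosome 14 had a median log2 fold change of 0.139, against -0.082 to 0.056 for the other autosomes (camera adjusted p = 1.8e-11 over 23 chromosomes). Chromosome 4 also passed in camera (median 0.056, adjusted p = 0.016), but not after the GC and length correction (0.24), without control A (0.32) or sgGLI1 B (0.070), or with no filter on low counts (0.40). Relative to the control mean, the median deviation of these genes was -0.019, -0.001 and 0.026 in control A, B and C, and 0.138, 0.156 and 0.135 in sgGLI1 A, B and C. Of these genes 111 were higher and 13 lower, so that chromosome 14 held 13.7% of the genes higher in sgGLI1 and 3.46% of the genes tested. Without control C 220 were higher and 32 lower (9.41% of the genes higher), and without control B, sgGLI1 A, B or C 35, 32, 32 and 35 were higher and 7, 7, 8 and 7 lower (12.4% to 14.1%). BMP4, which fell, is a gene of this chromosome that went the other way.

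The tables argue against a bias for GC content or gene length, since the median was 0.140 after each library was corrected for both, above the highest other autosome (0.036). They also argue against a single library, since the median was at least 0.135 without each library in turn. A few genes or 1 short segment are argued against, since 10 of 10 bins of neighbouring genes had a median above 0. Bins 1 to 9 lay at 0.097 to 0.174. The last bin, at 0.018, lay inside the range of the other autosomes (up to 0.056), so a large segment without that end is not argued against. More copies of chromosome 14, or of most of it, in part of the sgGLI1 cells may account for the shift, as the less and the more expressed genes both moved (medians of 0.129 and 0.143). Fewer copies in part of the control cells would give the same values and were not told apart from it by these counts. Whether such a difference arose by growth of a subclone after transduction, by the guide or by chance was not tested, and DNA copy number was not analysed here.

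The real split of the 6 libraries gave 1661 changed genes, and the highest of the other splits gave 0 in edgeR (up to 1630 genes at an unadjusted p under 0.05, against 4518 for the real split). Only 1 of 10 splits, the real one, gave as many, and 10 splits are too few for a share under 0.05. Each of the other splits mixes control and sgGLI1 libraries, so differences between the groups widen the spread within its sets. The 0 calls there are therefore no measure of what chance gives.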

How the results depend on the processing

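The GC and length correction, thinning to equal depth and leaving out chromosome 14 genes were chosen after seeing the data. Outside the fits with 1 library left out, 1489 values of named genes other than GLI1 kept their direction and side of the threshold, 28 newly passed, 26 no longer passed and 5 changed sign; for lists these were 317, 6, 8 and 27. No called list and no called gene among those named changed sign; of the 1661 calls, 2 changed sign with the GC and length correction. Where no cause is given, the cause was not tested. Deviations from the group mean per gene correlated at 0.044, -0.026 and -0.16 between same-lettered libraries A, B and C, so the letters did not pair them. By these deviations no control library correlated best with the sgGLI1 library of its own letter. With a replicate block 503 genes were higher and 465 lower, and GLI1 was at -0.48 (edgeR adjusted p = 0.087). With the GC and length correction 1941 were higher and 1898 lower, keeping 1617 of the 1661 calls, and 6 lists were higher. In simulated counts with GC trends, 155 of 200 changed genes were recovered with this correction and 105 without it. Unchanged genes called numbered 13 with it and 1 without it. The filter of 1 CPM, which tests fewer genes, left 39 higher and 75 lower by at least 2-fold. GLI1 missed the threshold with upper quartile scaling (-0.46), limma-voom (-0.50), thinning (-0.47) and without chromosome 14 genes (-0.49), with edgeR or limma adjusted p of 0.050 to 0.070. With an estimated correlation 0 lists were higher and 1 lower. Without 1 library at a time, genes higher ranged from 237 to 2337 (most without control C), genes lower from 227 to 2690, genes higher by at least 2-fold from 46 to 95, genes lower by at least 2-fold from 88 to 291, GLI1 from -0.55 to -0.36 and lists higher from 1 to 4. Fits with 5 libraries have fewer samples.

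Among named genes and lists, changes of sign were found only in those that did not pass. With the GC correction, SUFU was at 0.02, NR3C1 at -0.01, CYC1 at 0.03, FN1 at -0.03, and the list medians of glycolysis at 0.0126, BCL2 family at 0.0151 and p53 targets at 0.0473. With upper quartile scaling, IL7R was at 0, T cell identity at 0.0158, p53 targets at 0.0191, T-ALL factors at 0.0247 and ER stress at 0.0252. With DESeq2 size factors, p53 targets were at 0.00294, T-ALL factors at 0.00867 and ER stress at 0.00921; with library size alone, T cell activation was at -0.00127. With the 1 CPM filter, T cell activation was at -0.0105, NK markers at -0.161, p53 targets at 0.0139, histones at 0.0353 and BCL2 family at 0.0434. With no filter, lysosome was at -0.00157, T cell activation at -0.0424, B cell markers at -0.0701 and p53 targets at 0.0252. With members of 1 list only, T cell activation was at -0.00717, NF-kB targets at -0.0608 and p53 targets at 0.00473. Thinned, p53 targets were at 0.00121. Without chromosome 14 genes, T cell activation was at -0.00202, ER stress at 0.00104 and T-ALL factors at 0.0031. Without 1 library at a time, GLI3 ranged from -0.07 to 0.01, SUFU from -0.08 to 0.02, IL7R from -0.06 to 0.04, IGLL1 from -1.35 to 0.01 and CD79A from -0.04 to 0.32. List medians ranged from -0.0234 to 0.00245 (hedgehog), -0.0168 to 0.0295 (T-ALL factors), -0.0254 to 0.0175 (T cell identity), -0.069 to 0.0525 (T cell activation), -0.0112 to 0.0231 (p53), -0.147 to 0.024 (BCL2 family), -0.0275 to 0.0793 (interferon), -0.009 to 0.0144 (ER stress), -0.0514 to 0.00487 (glycolysis), -0.0504 to 0.0924 (B cell) and -0.062 to 0.0697 (epithelial). At these depths, genes near 3 counts per library, such as STON2 in control, have wide counting error.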

Other observations

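The test of neighbouring genes and the pairs named were chosen after the values of single genes were seen, as were the GC correction and the thinning of libraries. Several genes that changed at least 2-fold lay next to each other on a chromosome. MYO5B, a myosin motor, rose beside CCDC11 (3.16 on the log2 scale) on chromosome 18, from 1 count in each control library to 53, 55 and 55 counts in the sgGLI1 libraries (ratio 71.1, 95% counting interval 23.9 to 348). GNGT2 (4.16) and ABI3 (ratio 36.5, 95% counting interval 20.1 to 73.9), which overlap on chromosome 17, also rose together, as did KDELC2 (1.18) and EXPH5 (1.59) on chromosome 11. LYSMD2 (-1.92) and TMOD2 (-1.31), SLC43A2 (-1.34) and SCARF1 (-1.40), and TMIGD2 (-2.60) and FSD1 (-1.21) fell in pairs. These 6 pairs among 173 such protein-coding genes compare with a median of 1 and an upper limit of 4 in the central 95% of 10000 shuffles of the values over genes (permutation p = 0.002). Of the 6 pairs, 4 do not overlap in the annotation (permutation p = 0.026), which is at that limit of 4 and not above it, the bound set for this test before its result was seen. By that bound the count went as set for overlapping or shared transcription units, which stay open as the source of the excess.

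Genes of ribosome biogenesis fell with a mean log2 fold change of -0.23. A bias for GC content or gene length is argued against, as the mean was -0.204 after the correction of each library, with 36 of 48 genes falling. A single control library is argued against too, as the mean was -0.217 or farther from 0 without each control library in turn, although 6 genes fell without control B against 26 with all libraries. An effect of the GLI1 guide, by loss of GLI1 or by breaking DNA as such, stays open. So does a difference in growth, density or subclones between the cultures, and these were not tested.

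Small changes followed the GC content of genes: among the 3595 genes with the lowest GC content 252 were higher and 107 lower, and among the 3595 with the highest 63 were higher and 255 lower. This trend is consistent with a difference in GC bias between libraries that also exists within a group, since the largest correlation among the 6 pairs of the same group was 0.65, against -0.33 between groups. With all libraries thinned to the smallest total the correlation was -0.32. Thinning keeps the expected share of each gene in its library, so this shows only that unequal totals in the calculation did not make the trend. Causes in preparation or sequencing that go with depth were not tested. After the correction for GC content and length, 498 genes were higher and 442 lower among those with the lowest GC content, and 473 and 434 among those with the highest. The correction takes out any trend with GC content, whatever its source, so this balance does not bear on the cause. No biological explanation was tested.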
